A study of Mus musculus with 12 samples.

How the data were processed

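RNA of C2C12 myoblasts, C2C12 myotubes, EDL muscles and soleus muscles was hybridized to 12 one-colour Agilent mouse arrays, 3 per group. The arrays sat on 3 slides of 4 arrays, each slide holding 1 array of every group, so the replicate number is the slide. Slide 1 was scanned on another day than the other slides, and array position on the slide went with the group on every slide, so position and group cannot be told apart.

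The deposited scanner files hold, per the file headers, the processed signal of each spot as an intensity made by Agilent Feature Extraction 10.5.1.1, background-subtracted and detrended within the array and not normalized between arrays. Among the other columns, per the file headers, are flags of 0 or 1 for spots well above background, saturated or outlying. The deposited table of the authors' values has 41267 probes and also holds an intensity on the linear scale; its between-array normalization is not stated in words. Its highest value was 608000 on every array, the array medians were 123 to 283, and 4913 to 11499 probes were missing per array. Across probes its log2 values correlated with those of the scanner files, with a lowest r of 0.9976 (EDL replicate 2). Probes are not independent replicates. These values were used as an alternative only.

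Of each array, 43379 spots were not controls, and 68 to 140 spots with an outlier flag were left out. No spot was saturated. Spots of the same probe were averaged, which gave 41174 probes. Probes were named by accession (24375), symbol (6301), synonym (2426) or another accession (2) in the reference gene table, and 8070 kept the name of the file; this gave 27597 gene names. Coordinates are those of the array design, in build mm8, while the reference table follows a later build and was used for names only. The processed signal was taken to log2 and each array's 75th percentile was subtracted, with a constant of 9.71 added back. A probe was kept if it was well above background on all 3 arrays of at least 1 group (28618 probes), and a gene was represented by its kept probe with the highest mean, which left 18870 genes.

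Differences were tested with limma 3.58.1 in R 4.3.3 (with version 1.17.8 of the data.table package), by lmFit and eBayes on all 12 arrays with 4 group means and no block (8 residual and 1.76 prior degrees of freedom), two-sided. Values of p were adjusted by Benjamini-Hochberg over all genes tested in a comparison, and a gene was called at an adjusted p under 0.05 and an absolute log2 difference of at least 1. Of 6 comparisons, 4 were the main ones (myotube minus myoblast, EDL minus myotube, soleus minus myotube, soleus minus EDL), and both muscles minus myoblast completed them. These p-values measure only the spread between these samples: the labels do not say whether the cultures of a group were grown separately, and each muscle sample pooled both hind limbs of 1 mouse.

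Gene lists, 28 with 423 entries of which 13 were not measured, were written before the data were examined and tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists within a comparison. They were the core dNTP enzymes; de novo dNTP synthesis and S phase supply; mitochondrial deoxynucleotide salvage and nucleotide kinases; deoxynucleotide breakdown; nucleoside and mitochondrial nucleotide transporters; mitochondrial DNA replication and transcription; nuclear DNA replication; mitosis and G2; cell cycle inhibitors; p53 targets; myogenic regulators; embryonic and neonatal muscle genes; fast and slow fibre contractile and calcium genes. The rest were glycolysis and glycogen, the TCA cycle, nuclear-encoded oxidative phosphorylation, fatty acid uptake and oxidation, mitochondrial biogenesis regulators, markers of endothelium, macrophages and leukocytes, fibroblasts and connective tissue, adipocytes, Schwann cells, erythroid cells, and smooth muscle and pericytes, immediate early and dissociation stress genes, and the unfolded protein response. The count of called members adjusted over the list alone equalled that over all genes for all 28 lists in every comparison except soleus minus myotube, where it did for 26.

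The genes named were chosen by a rule written before the data were examined. It names all core dNTP enzymes in each comparison; in the main comparisons the 4 highest and 4 lowest called genes with a symbol whose groups did not overlap and which were above background on every array of both groups; and up to 3 members with the largest called differences of each other list that passed, with the first listed member not called as a contrast. The contrasts entered the alternatives, and only some are printed. Some genes that the rule names are not reported here. Genes named outside the rule are given as chosen after their values were seen. Where a group was not well above background on any array, the fold is a lower bound ("at least"), computed per array against the higher of the lowest well-above-background signal and the probe's own signal. In list medians this was read on the tested probe, and a member whose bound was 0 or less entered as no difference.

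Residuals of arrays sharing a replicate number correlated in all 18 pairs, with r of 0.225 to 0.660 across genes, all over 0.1, so the numbers pair the samples. Arrays of a number share a slide. The correlations of EDL with soleus were 0.436 to 0.660, and the labels do not say whether these also came from the same mouse. A fit with the replicate as a block was an alternative, and differences were also computed within each slide. The other alternatives were quantile normalization, scaling by 10 spike-in probes, normexp background correction with an offset of 50, no filter on dim probes, a filter on all 12 arrays, the authors' values, eBayes with trend and robust settings, the mean over all tested probes of a gene, a fit of only the compared groups, and leaving out each of the 6 arrays of a comparison in turn. A fit without replicate 1 of every group was added after the data were seen.

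The procedure was tested on simulated data with added changes. In a myotube minus myoblast layout it recovered 79.4% of genes changed by a log2 of 1.5, 90.9% at 2 and 100% at 4, with 4 unchanged genes called; in a soleus minus EDL layout the shares were 79.4%, 86.4% and 98.5%, with 2 unchanged genes called. The list test found the 1 shifted list and called 0 of the others. Simulated genes and arrays were drawn independently, without correlation between genes or a shared slide effect. Only a small share of genes was changed. The simulation therefore does not tell how many false gene or list calls to expect in the real data.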

Results

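Gene expression was measured on 12 one-colour arrays of mouse muscle RNA. The 4 groups held 3 arrays each. C2C12 myoblasts are dividing precursors of a mouse muscle cell line, collected at about 50% confluence. C2C12 myotubes are the fused cells obtained after 96 hours of differentiation, purified to lower the share of mononucleated cells. The extensor digitorum longus (EDL), a fast glycolytic hind limb muscle, and the soleus, a slow oxidative one, came from 3-month-old male CD1 mice. Probes well above background made up 63.2% to 70.8% of all probes on the myoblast arrays, 61.3% to 68.6% on the myotube arrays, 57.4% to 72.9% on the EDL arrays and 57.6% to 69.1% on the soleus arrays. Across probes, the lowest r between replicate arrays was 0.985 (myoblast), 0.981 (myotube), 0.974 (EDL) and 0.976 (soleus). EDL correlated with soleus arrays with r of 0.959 to 0.978. The lowest correlations between groups were those of myoblasts with EDL, 0.832 to 0.843. Probes are not independent replicates. After filtering, 18870 genes were tested. Levels are normalized log2 signals given as mean ± SD with n = 3 arrays per group, differences are on the log2 scale with their standard error (SE), and the number of arrays limits the precision.

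The unscaled 75th percentile of signal was 1110 to 1649 on myoblast and 1065 to 1290 on myotube arrays, against 480 to 613 on EDL and 476 to 640 on soleus arrays. The spike-in control RNA differed little between cultures and muscles (0.08 higher in muscle on the log2 scale). Changes below are relative to the 75th percentile. Scaling by the spike-in signal instead moved every gene by -0.35 in myotube minus myoblast, -0.99 in EDL minus myotube, -1.20 in soleus minus myotube and -0.22 in soleus minus EDL.

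The series title names genes that regulate the mitochondrial pool of deoxynucleotides (dNTPs). For this topic a list of 14 core enzymes that make, salvage or break down dNTPs was written here before the data were examined. In the array design's coordinates (mouse build mm8), their probes lie at chromosome 7, 102342530 to 102342590, plus strand (Rrm1); chromosome 12, 25302833 to 25302889, plus (Rrm2); chromosome 15, 37868655 to 37868714, minus (Rrm2b); chromosome 11, 117631881 to 117631940, minus (Tk1); and chromosome 8, 107116423 to 107116482, minus (Tk2). Those of Dck (chromosome 5, 89857207 to 89857265, plus), Dguok (chromosome 6, 83445921 to 83445980, minus), Tyms (chromosome 5, 30391852 to 30391911, minus), Dctd (chromosome 8, 49639938 to 49639997, plus) and Dut (chromosome 2, 124948847 to 124948906, plus) were placed in the same way. The remaining probes lie on chromosome 2, 156796349 to 156797702, minus (Samhd1, a span longer than the probe), chromosome 11, 59692425 to 59692484, plus (Nt5m), chromosome 11, 115306535 to 115306594, minus (Nt5c) and chromosome 15, 89199857 to 89199916, minus (Tymp). No gene models of that build were used here, so exons and untranslated regions are not given.

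**Figure D1:**
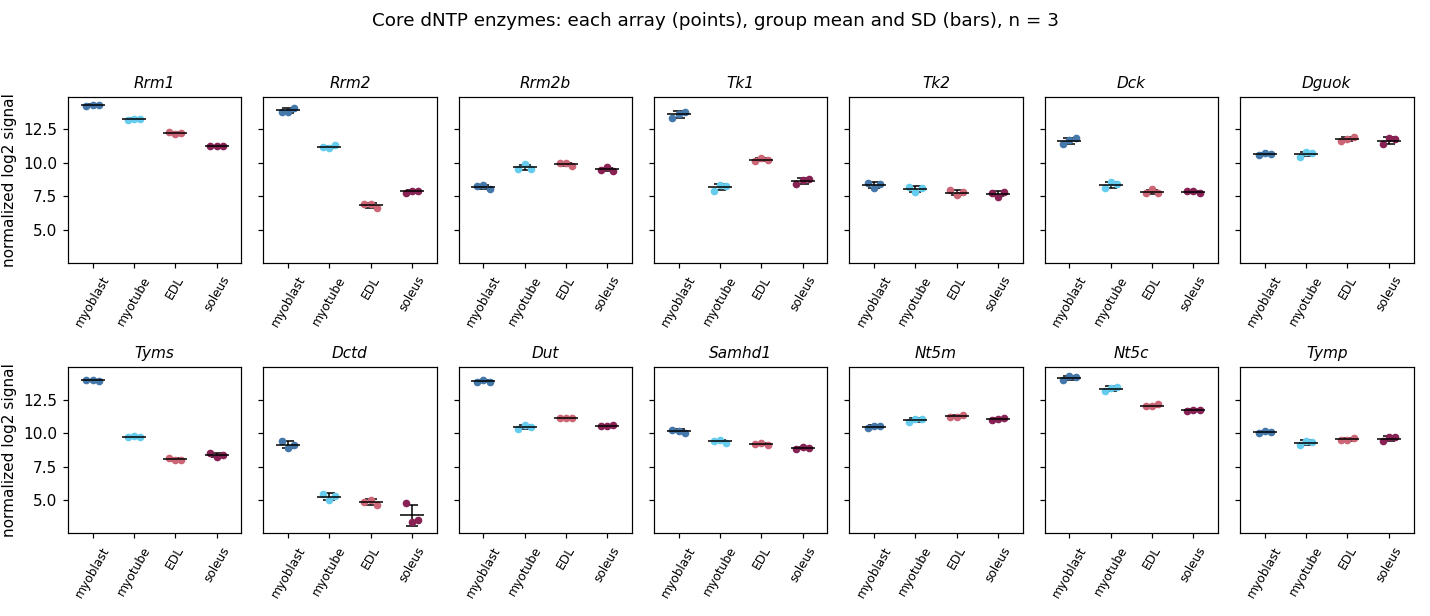
Normalized log2 signal (vertical axis) of the 14 core dNTP enzymes in myoblasts, myotubes, EDL and soleus; points are single arrays, long bars the group means and short bars the SD (n = 3 arrays). Tk1 stands at 13.62 in myoblasts, 8.17 in myotubes, 10.24 in EDL and 8.65 in soleus, and Tk2 between 7.69 and 8.35 in all 4 groups.

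The comparison of myotubes with myoblasts asks how the dNTP enzymes differ between dividing precursors and fused muscle cells. Tk1, the cytosolic thymidine kinase of S phase, fell 43.5-fold, from 13.62 ± 0.24 to 8.17 ± 0.23 (difference -5.44, SE 0.16, adjusted p = 9.9e-10). Thymidylate synthase (Tyms) fell by 4.21 (SE 0.09), dCMP deaminase (Dctd) by 3.88 (SE 0.33), dUTPase (Dut) by 3.44 (SE 0.09) and deoxycytidine kinase (Dck) by 3.29 (SE 0.14). Of the ribonucleotide reductase subunits, Rrm2 fell by 2.72 (SE 0.12, adjusted p = 1.4e-08) and Rrm1 by 1.06 (SE 0.07), while Rrm2b, the p53-inducible small subunit, rose by 1.45, from 8.21 ± 0.15 to 9.66 ± 0.20 (SE 0.13, adjusted p = 3.1e-06). Both mitochondrial deoxynucleoside kinases missed the threshold: Tk2 differed by -0.30 (SE 0.15, adjusted p = 0.103) and Dguok by 0.0033 (SE 0.14, adjusted p = 0.987; -0.35 with spike-in scaling). In the whole list 8 of 14 enzymes changed, 1 higher and 7 lower, and 8 also when adjusted over the list alone. The list's median was -0.94 (adjusted p = 7.6e-04; adjusted p = 0.110 with an estimated correlation). Among the enzymes not called, Samhd1 differed by -0.77 (with probes of opposite sign), Nt5c by -0.81, Tymp by -0.81 and Nt5m by 0.47. With spike-in scaling Samhd1 (-1.12, the same probe), Nt5c (-1.16) and Tymp (-1.16) were called.

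Genes of cell division fell as groups. All 22 genes of nuclear DNA replication were lower (median -3.33, adjusted p = 2.1e-13), among them the origin licensing factor Cdc6 (-5.94, SE 0.17), Mcm5 (-5.33, SE 0.18) and Mcm10 (-5.20, SE 0.18). All 18 genes of mitosis and G2 were lower (median -5.82, or -5.77 with the member not well above background at its bound; adjusted p = 9.8e-12), such as cyclin B1 (Ccnb1, -6.66, SE 0.41), Bub1b (-6.24, SE 0.26) and Bub1 (-6.20, SE 0.18). Of 18 genes of de novo dNTP synthesis and S phase supply, 13 fell and 1 rose (median -1.64, adjusted p = 2.4e-07). The riser, Shmt1 (1.01, SE 0.22), was chosen after its values were seen. Of 15 deoxynucleotide breakdown genes 5 fell (median -0.81, adjusted p = 0.0103; adjusted p = 0.0931 with an estimated correlation). These included adenosine deaminase (Ada, -5.07, SE 0.09), purine nucleoside phosphorylase (Pnp, -2.98, SE 0.10) and uridine phosphorylase Upp1, which was not well above background on any myotube array and at least 2.00-fold lower. The other fallers, Cda (-1.48) and Nt5e (-1.33), were chosen after their values were seen.

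Muscle genes rose. All 15 fast fibre contractile and calcium genes were higher (median 6.43, or 6.42 with 1 member at its bound; adjusted p = 2.7e-11). They included Mybpc2 (12.19, SE 0.18; above background on 1 of 3 myoblast arrays), the fast myosin Myh2 (10.03, SE 0.12) and the calcium store protein Casq1 (9.91, SE 0.13). Of 12 slow fibre genes 11 rose (median 6.33, adjusted p = 2.2e-07; adjusted p = 0.0931 with an estimated correlation), among them Myl2 (12.17, SE 0.37; above background on 1 of 3 myoblast arrays), Myoz2 (8.82, SE 0.09) and Casq2 (7.23, SE 0.08). Tpm3, the member that fell (-1.89, SE 0.08), was chosen after its values were seen. Of 11 embryonic and neonatal muscle genes 10 rose (median 3.97, adjusted p = 1.2e-06). Myl4 stood at 7.41 (SE 0.09), Myh8 at 6.78 (SE 0.11) and Myh3 at 6.20 (SE 0.20), while the cadherin Cdh15 differed by 0.34 (-0.02 with spike-in scaling) and was not called. Of 19 glycolysis and glycogen genes 10 rose, or 9 without Phkg1 (chosen after its values were seen), whose bound leaves no measured rise (median 1.19, or 0.84 with 2 members at their bound; adjusted p = 0.0103; adjusted p = 0.120 with an estimated correlation), led by glycogen phosphorylase Pygm (7.10, SE 0.09) and Pgam2 (5.79, SE 0.17). Fbp2 was at least 7.78-fold higher and not well above background on any myoblast array, but stood at -0.35 with normexp background correction. Of 43 nuclear-encoded oxidative phosphorylation genes 6 rose (median 0.51, adjusted p = 4.1e-05; adjusted p = 0.433 with an estimated correlation), including the muscle isoforms of cytochrome c oxidase subunits Cox6a2 (8.42, SE 0.25), Cox8b (8.12, SE 0.16) and Cox7a1 (3.81, SE 0.16). Of 22 fatty acid genes 12 rose (median 1.06, adjusted p = 6.4e-05), such as the transporter Cd36 (6.80, SE 0.15), Acsl6 (5.75, SE 0.09) and Fabp3 (5.19, SE 0.11), and lipoprotein lipase (Lpl, -1.25, SE 0.08), chosen after its values were seen, fell. Of 14 immediate early and dissociation stress genes 5 rose and 1 fell (median 0.62, adjusted p = 0.0342; adjusted p = 0.0999 with an estimated correlation). Socs3 rose by 4.42 (SE 0.07), Fos by 2.64 (SE 0.17) and Nr4a1 by 1.85 (SE 0.09). The fall of Dnajb1 (-1.26) and the rises of Junb (1.12) and Zfp36 (1.24) were chosen after their values were seen.

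Outside these groups, the highest differences of genes eligible by the rule included the deubiquitinase-family gene Otud7a (8.88, SE 0.21) and Fxyd6 (8.83, SE 0.24). The lowest by the rule were Chst1 (-7.23, SE 0.19), the water channel Aqp1 (-7.10, SE 0.12), the anchoring protein Akap12 (-7.01, SE 0.12) and cyclin D1 (Ccnd1, -6.95, SE 0.09). In all, 3634 genes were higher and 3054 lower in myotubes (54.3% of calls higher), against 2453 higher and 4026 lower (37.9%) with spike-in scaling. The groups did not overlap for 68.9% of genes, where chance gives 10%. Lists that did not pass, with adjusted p from 0.0783 to 0.915, were mitochondrial salvage (median -0.41), nucleotide transporters, mitochondrial DNA replication, cell cycle inhibitors, p53 targets (median 0.84), myogenic regulators, the TCA cycle (median 0.45), mitochondrial biogenesis, the unfolded protein response, and the endothelial, macrophage, fibroblast, adipocyte, Schwann cell, erythroid and smooth muscle markers. The median was positive and the mean negative for mitochondrial DNA replication (0.12 and -0.01), the reverse held for myogenic regulators (-0.28 and 0.22), and the macrophage test pointed down at a median of 0.12 (with 4 members at their bound the median was 0). With spike-in scaling the medians of mitochondrial DNA replication (-0.24), cell cycle inhibitors (0.05 to -0.30), macrophage (-0.24) and erythroid markers (0.17 to -0.19) turned negative. With 28 lists tested, 12 passed and 6 of these passed with an estimated correlation. Within each of the 3 slides, all 45 called genes named by the rule and all 12 passing lists kept their sign, with Tk1 at -5.53 to -5.35. With normexp background correction Rrm1 (-0.93), Rrm2b (0.95), Upp1 (-1.57) and the breakdown list (median -0.70) were no longer called. The immediate early list was no longer called with spike-in scaling (median 0.27), with means over probes (0.49), without replicate 1 of every group (0.62) or with only the compared groups fitted (0.62). The p53 list passed with quantile normalization (0.84), normexp (0.95) and the authors' values (0.85), the TCA cycle (0.48) and fibroblast (-1.29) lists with normexp, the biogenesis list as a mean over probes (0.63), and the smooth muscle list without a filter (-0.98).

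The comparison of EDL with myotubes sets differentiated cells in culture against a fast muscle of adult mice. In EDL the ribonucleotide reductase subunit Rrm2 was a further 20.8-fold lower, at 6.82 ± 0.16 against 11.20 ± 0.09 in myotubes (difference -4.38, SE 0.12, adjusted p = 3.0e-10), and Rrm1 fell by 1.04 (SE 0.07). Tyms fell by 1.69 (SE 0.09; 2 of its 3 probes pointed this way) and the 5'-nucleotidase Nt5c by 1.26 (SE 0.11). Tk1 was 4.18-fold higher in EDL, 10.24 ± 0.13 against 8.17 ± 0.23 (difference 2.06, SE 0.16, adjusted p = 1.0e-06; 1.08 and not called with spike-in scaling). The mitochondrial deoxyguanosine kinase Dguok rose by 1.12 (SE 0.14, adjusted p = 3.3e-05; 0.14 and not called with spike-in scaling). Rrm2b differed by 0.23 (SE 0.13, adjusted p = 0.123; -0.75 with spike-in scaling) and Tk2 by -0.26 (SE 0.15, adjusted p = 0.142; -1.25 and called with spike-in scaling). In the list 6 of 14 enzymes changed, 2 higher and 4 lower, and 6 also when adjusted over the list alone (median -0.23, adjusted p = 0.346). Not called were Dck (-0.52), Samhd1 (-0.20, with probes of opposite sign), Dctd (-0.41, above background on 1 of 3 EDL arrays), and Dut (0.69), Nt5m (0.30) and Tymp (0.25), which turned to -0.30, -0.69 and -0.74 with spike-in scaling. As a mean over all tested probes Dck (-1.06), Dctd (-1.11) and Samhd1 (1.19) were called, and with spike-in scaling Dck (-1.51), Dctd (-1.39) and Samhd1 (-1.19).

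Mitochondrial and metabolic genes were higher in EDL as groups, on arrays where markers of other cell types were higher too. All 19 TCA cycle genes rose (median 2.01, adjusted p = 6.7e-07), led by Idh3a (3.55, SE 0.10), Sdha (3.45, SE 0.14) and Idh3b (3.19, SE 0.07). All 43 oxidative phosphorylation genes rose (median 1.96, adjusted p = 1.9e-11; adjusted p = 0.116 with an estimated correlation). Cox7a1 stood at 6.09 (SE 0.16), Cox8b at 3.89 (SE 0.16) and Cox6a2 at 3.40 (SE 0.25); with spike-in scaling 18 were called and the median was 0.97. All 19 glycolysis genes rose (median 2.47, adjusted p = 3.5e-07), including Phkg1 (11.29, SE 0.47; above background on 1 of 3 myotube arrays), Gpd1 (7.63, SE 0.12) and Fbp2 (5.30, SE 0.39). Of 22 fatty acid genes 20 rose (median 1.85, adjusted p = 6.5e-06), among them Cpt1b, which carries fatty acids into mitochondria (7.47, SE 0.10), Lpl (7.10, SE 0.08) and Etfb (2.80, SE 0.15). Of 11 mitochondrial biogenesis regulators 9 rose (median 1.83, adjusted p = 0.00374; adjusted p = 0.0544 with an estimated correlation), with Perm1 at 10.14 (SE 0.43), Ppara at 5.01 (SE 0.20) and the coactivator Ppargc1a at 4.74 (SE 0.24). Endothelial markers were higher in 12 of 12 genes (median 7.0, or 6.12 with 4 members at their bound; adjusted p = 8.4e-06), such as Emcn (at least 636-fold), Cdh5 (at least 426-fold) and Flt1 (8.70, SE 0.11). Macrophage markers rose in 11 of 14 genes (median 5.17, or 3.40 with 6 at their bound; adjusted p = 2.8e-04), with Lyz2 at 8.50 (SE 0.10), C1qc at least 56.1-fold and Cd163 at least 81.2-fold higher. Of 14 fibroblast markers 12 rose and Col5a1 (-1.92, chosen after its values were seen) fell (median 4.12, adjusted p = 1.4e-04; adjusted p = 0.0711 with an estimated correlation). Among the risers Thy1 was at least 294-fold, Tnmd at least 90.9-fold and Lum 9.96 (SE 0.67; above background on 1 of 3 myotube arrays) higher. All 6 adipocyte markers rose (median 5.29, or 4.40 with 3 at their bound; adjusted p = 0.00548; adjusted p = 0.0961 with an estimated correlation), including Fabp4 (11.003, SE 0.70), Cfd (at least 242-fold) and Adipoq (at least 17.7-fold). Of 7 Schwann cell markers 6 rose (median 2.99, adjusted p = 0.0045; adjusted p = 0.0578 with an estimated correlation), among them Mbp (7.43, SE 0.08) and S100b (3.68, SE 0.14). Of 9 smooth muscle markers 6 rose (median 1.89, adjusted p = 0.00259), with Rgs5 at least 1477-fold higher, Myh11 at 6.32 (SE 0.17; above background on 2 of 3 myotube arrays) and Notch3 at 2.88 (SE 0.17). The 3 erythroid markers had a median of 7.72 (6.18 with 1 at its bound) and did not pass (adjusted p = 0.0678). They passed with quantile normalization (7.16), spike-in scaling (6.74), normexp (3.59), the authors' values (5.54), without replicate 1 of every group (7.88) and without myotube replicate 1 (7.79).

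All 15 fast fibre genes rose in EDL (median 2.44, adjusted p = 8.6e-06), among them the calcium buffer Pvalb (9.62, SE 0.25), the calcium pump Atp2a1 (5.03, SE 0.22) and Mybpc2 (4.33, SE 0.18). Of 12 slow fibre genes 10 fell (median -1.80, adjusted p = 2.4e-05; adjusted p = 0.0961 with an estimated correlation), including Tnnc1 (-5.92, SE 0.12), Casq2 (-5.76, SE 0.08) and Tnni1 (-5.41, SE 0.09). Of 11 embryonic and neonatal genes 9 fell (median -4.99, adjusted p = 1.1e-05), with the fetal acetylcholine receptor subunit Chrng at -9.69 (SE 0.13), Myl4 at -6.89 (SE 0.09) and Chrnd at -6.65 (SE 0.09). The members that rose against these lists, Myl3 (1.35) and Myh8 (1.54), were chosen after their values were seen. The Myl3 value rests on 1 probe, and its probes differ. In soleus minus EDL that probe gave 0.68 and the mean over all tested probes 3.41. Of 22 nuclear replication genes 11 had a called fall, or 10 without Orc1, whose bound leaves no measured fall (median -0.90, or -0.53 with Orc1 at no difference; adjusted p = 0.00155), such as Cdt1 (-2.45, SE 0.11), Prim1 (-2.32, SE 0.09) and Mcm10 (-2.31, SE 0.18; above background on 2 of 3 EDL arrays). Of 18 mitosis and G2 genes 15 had a called fall, or 14 without Kif11, whose bound leaves none either (median -2.17, or -1.68 with 7 members at their bound; adjusted p = 2.3e-04). Orc1 and Kif11 were chosen after their values were seen. Birc5 stood at -3.79 (SE 0.12; compared on 2 of the 3 slides), and Bub1 was at least 3.51-fold and Cdk1 at least 8.95-fold lower (1 of 2 Cdk1 probes pointed this way). Pola2 (2.06) and Aurka (3.17), the members of these lists that rose, were chosen after their values were seen. Of 14 p53 targets 10 fell and 2 rose (median -1.24, adjusted p = 0.00282; adjusted p = 0.0631 with an estimated correlation). The cell cycle inhibitor Cdkn1a fell by 6.97 (SE 0.14) and Plk2 by 3.87 (SE 0.12), whereas Perp rose by 4.03 (SE 0.10) and Ccng1, chosen after its values were seen, by 1.56. Of 14 immediate early genes 9 fell (median -1.41, adjusted p = 9.0e-04), with Socs3 at -4.36 (SE 0.07), Junb at -3.37 (SE 0.14) and Egr1 at -3.03 (SE 0.09), and Nr4a1 (2.17, chosen after its values were seen) rose.

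Outside these groups the ribosomal protein paralog Rpl3l (10.71, SE 0.23) and Cmya5 (10.69, SE 0.11) were among the highest differences of genes eligible by the rule. Msln (-8.98, SE 0.14) and the lipoxygenase Alox5 (-8.39, SE 0.07) were among the lowest. In all, 5357 genes were higher and 3691 lower in EDL (59.2% of calls higher), against 2644 higher and 7717 lower (25.5%) with spike-in scaling. The groups did not overlap for 76.3% of genes, where chance gives 10%. De novo dNTP synthesis (median -0.31), cell cycle inhibitors (-0.37) and the unfolded protein response (-0.55) did not pass (adjusted p from 0.0782 to 0.465). Mitochondrial salvage, deoxynucleotide breakdown, nucleotide transporters, mitochondrial DNA replication and myogenic regulators did not pass either (adjusted p from 0.346 to 0.999), and their medians of 0.03, 0.25, 0.75, 0.40 and 0.64 turned to -0.96, -0.74, -0.24, -0.59 and -0.35 with spike-in scaling. The tests of salvage and breakdown pointed down against these medians, and the mean of the myogenic regulators was -0.25. The unfolded protein response passed with normexp (-0.62) and without a filter (-0.55). Of the 28 lists, 18 passed and 11 of these passed with an estimated correlation. Within each slide, all 64 called genes that the rule names and every slide measured (Birc5 was not among them) and all 18 passing lists kept their sign, with Tk1 at 1.92 to 2.22. With normexp background correction Mcm10 (-0.79), Cdk1 (-1.15), Bub1 (-0.44), Adipoq (2.08) and the mitosis list (median -0.38) were no longer called. Tyms (-0.81) was not called as a mean over probes, and the mitosis (-1.88) and macrophage (1.00) lists did not pass among genes above background on all 12 arrays.

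The comparison of soleus with myotubes sets the same cultures against a slow muscle. In soleus Rrm2 was 10.1-fold lower, at 7.87 ± 0.10 (difference -3.33, SE 0.12, adjusted p = 2.2e-09), Rrm1 fell by 1.99 (SE 0.07), Nt5c by 1.62 (SE 0.11) and Tyms by 1.38 (SE 0.09; 2 of 3 probes). Dctd was not well above background on any soleus array and at least 2.19-fold lower, but stood at 1.06 with normexp background correction. Dguok rose by 1.01 (SE 0.14, adjusted p = 7.6e-05) and turned to -0.19 with spike-in scaling. Tk1 differed by 0.48 (SE 0.16, adjusted p = 0.0240; -0.73 with spike-in scaling), below the log2 threshold of 1, Tk2 by -0.36 (SE 0.15, adjusted p = 0.0534) and Rrm2b by -0.14 (SE 0.13, adjusted p = 0.335). Both Tk2 (-1.56) and Rrm2b (-1.35) were called with spike-in scaling. In the list 6 of 14 enzymes changed, 1 higher and 5 lower, and 6 also when adjusted over the list alone (median -0.44, adjusted p = 0.0741), and the list passed with spike-in scaling (-1.64) and without a filter (-0.44). Dck (-0.54), Samhd1 (-0.52, with probes of opposite sign) and Tymp (0.31, or -0.90 with spike-in scaling) were not called, nor were Dut and Nt5m, both at 0.11 and at -1.09 and called with spike-in scaling. Dck was called as a mean over probes (-1.12) and with spike-in scaling (-1.74), and Samhd1 with spike-in scaling (-1.72). Of 18 de novo dNTP synthesis genes 6 fell (median -0.60, adjusted p = 0.0418; adjusted p = 0.182 with an estimated correlation), including the CTP synthase Ctps (-1.41, SE 0.10).

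As in the EDL comparison, gene groups of oxidative metabolism were higher in soleus on arrays with higher markers of other cell types. All 19 TCA cycle genes rose (median 1.99, adjusted p = 3.2e-07), with Idh3b at 3.18 (SE 0.07), Sdha at 3.07 (SE 0.14) and Idh3a at 2.76 (SE 0.10). All 43 oxidative phosphorylation genes rose (median 1.92, adjusted p = 2.1e-12; adjusted p = 0.111 with an estimated correlation). Cox7a1 stood at 6.0 (SE 0.16), Cox8b at 4.03 (SE 0.16) and Cox6a2 at 3.54 (SE 0.25); with spike-in scaling 11 were called and the median was 0.71. Of 22 fatty acid genes 21 rose (median 2.65, adjusted p = 1.0e-07), led by Lpl (8.78, SE 0.08), Cpt1b (8.24, SE 0.10) and Acadm (3.80, SE 0.11). Of 11 biogenesis regulators 8 rose (median 1.97, adjusted p = 0.00168), among them Perm1 (10.95, SE 0.43), Ppara (6.20, SE 0.20) and Ppargc1a (4.99, SE 0.24). Of 19 glycolysis genes 14 rose (median 1.39, adjusted p = 1.9e-05). Spike-in scaling shifts every gene of this comparison by -1.20, which takes up most of that median. Phkg1 stood at 7.55 (SE 0.47, above background on 1 of 3 myotube arrays), Gpd1 at 4.39 (SE 0.12) and Fbp2 at 3.70 (SE 0.39). All 12 endothelial markers rose (median 7.26, or 6.37 with 4 at their bound; adjusted p = 3.8e-06), such as Emcn (at least 758-fold), Cdh5 (at least 499-fold) and Kdr (9.07, SE 0.32; above background on 2 of 3 myotube arrays). Macrophage markers rose in 12 of 14 genes (median 5.15, or 3.23 with 6 at their bound; adjusted p = 6.8e-05), with Lyz2 at 8.62 (SE 0.10), C1qc at least 62.5-fold and Cd163 at least 70.3-fold higher. Of 14 fibroblast markers 13 rose and Col5a1 (-2.34, chosen after its values were seen) fell (median 3.71, adjusted p = 6.8e-05; adjusted p = 0.0672 with an estimated correlation). Risers included Thy1 (at least 201-fold), Tnmd (at least 130-fold) and Lum (9.97, SE 0.67; above background on 1 of 3 myotube arrays). All 6 adipocyte markers rose (median 6.82, or 5.93 with 3 at their bound; adjusted p = 0.00262; adjusted p = 0.0738 with an estimated correlation), with Fabp4 at 11.51 (SE 0.70), Cfd at least 706-fold and Adipoq at least 47.7-fold higher. Of 7 Schwann cell markers 6 rose (median 3.98, adjusted p = 0.00193), among them Mbp (8.76, SE 0.08) and S100b (4.45, SE 0.14). Of 9 smooth muscle markers 7 rose (median 2.26, adjusted p = 5.3e-04), with Rgs5 at least 1413-fold higher, Myh11 at 6.97 (SE 0.17; above background on 2 of 3 myotube arrays) and Notch3 at 2.91 (SE 0.17). The 3 erythroid markers had a median of 6.72 (5.17 with 1 at its bound) and did not pass (adjusted p = 0.0883), with 2 called and 3 when adjusted over the list alone. They passed with spike-in scaling (5.51), the authors' values (4.48) and without replicate 1 of every group (6.89).

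Many, but not all, contractile genes were higher in soleus than in myotubes. Of 12 slow fibre genes 8 rose (median 2.02, adjusted p = 0.00303; adjusted p = 0.213 with an estimated correlation), with Myl2 at 4.16 (SE 0.37), Ankrd2 at 2.66 (SE 0.13) and Myh7, the slow myosin, at 2.56 (SE 0.12). Of 15 fast fibre genes 10 rose (median 1.27, adjusted p = 0.00303; adjusted p = 0.0779 with an estimated correlation), including Pvalb (4.84, SE 0.25), Myh2 (4.72, SE 0.12) and Atp2a1 (3.29, SE 0.22). The fast fibre list did not pass with quantile normalization (0.54), the authors' values (0.52) or normexp (0.83), nor the slow fibre list with normexp (1.55). The spike-in shift of -1.20 takes up nearly all of the fast fibre median of 1.27. The members of these lists that fell, Casq2 (-2.28) and Actn3 (-2.54), and Acsl6 of the fatty acid list (-1.52), were chosen after their values were seen. Of 11 embryonic and neonatal genes 9 fell (median -3.66, adjusted p = 3.8e-05), among them Chrng (-8.06, SE 0.13), Myl4 (-6.86, SE 0.09) and Chrnd (-6.49, SE 0.09), and Myh8 (1.37), chosen after its values were seen, rose. Of 22 nuclear replication genes 12 fell (median -1.04, or -0.84 with 1 at its bound; adjusted p = 0.00303), with the primase subunits Prim1 at -3.20 (SE 0.09) and Prim2 at -2.14 (SE 0.10). Pola2 (2.73, SE 0.20) and Gins1 (1.59, chosen after its values were seen) rose. Of 18 mitosis and G2 genes 14 fell (median -1.87, or -1.55 with 6 at their bound; adjusted p = 1.1e-04) and Cenpa (1.85), chosen after its values were seen, rose; the median turned to 0.28 with normexp background correction. Bub1 was at least 4.31-fold and Aurkb at least 3.76-fold lower, both not well above background on any soleus array and at 0.54 and 0.73 with normexp, and Cdk1 fell by 3.27 (SE 0.24; above background on 1 of 3 soleus arrays, 1 of 2 probes). Of 14 p53 targets 9 fell (median -1.60, adjusted p = 0.00389; adjusted p = 0.0738 with an estimated correlation). Cdkn1a stood at -5.84 (SE 0.14), Gadd45a at -3.77 (SE 0.09) and Plk2 at -3.71 (SE 0.12), and Perp (3.24), chosen after its values were seen, rose. Of 14 immediate early genes 6 fell and 1 rose, against 8 changed when adjusted over the list alone (median -0.98, adjusted p = 0.0203; adjusted p = 0.0672 with an estimated correlation). Socs3 (-5.31, SE 0.07), Junb (-3.48, SE 0.14) and Egr1 (-2.91, SE 0.09) were among the fallers. Hspa1a (2.72), chosen after its values were seen, rose, and Fosb (-1.01, SE 0.43, adjusted p = 0.0563) was not called. Fosb was called with quantile normalization (-1.42), spike-in scaling (-2.22) and the authors' values (-1.45), and at -1.01 with the replicate block, the filter on all 12 arrays, eBayes with trend and robust settings, or only the compared groups fitted.

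Outside these groups Sln, a regulator of the calcium pump (11.26, SE 0.14), and Ppp1r1a (11.06, SE 0.21) were among the highest differences of genes eligible by the rule. Mybph (-9.67, SE 0.10), Msln (-9.13, SE 0.14), Gsta1 (-8.86, SE 0.21) and Frmpd1 (-8.12, SE 0.20) were the lowest by the rule. In all, 4917 genes were higher and 3646 lower in soleus (57.4% of calls higher), against 2248 higher and 9173 lower (19.7%) with spike-in scaling. The groups did not overlap for 74.1% of genes, where chance gives 10%. Mitochondrial salvage (median -0.25, mean 0.07) and the unfolded protein response (median -0.36) did not pass (adjusted p = 0.511 and 0.121), the latter passing with normexp (-0.78) and without a filter (-0.36). Deoxynucleotide breakdown, nucleotide transporters, mitochondrial DNA replication, cell cycle inhibitors and myogenic regulators did not pass either (adjusted p from 0.511 to 0.957), and their medians of 0.11, 0.48, 0.31, 0.18 and 0.89 turned to -1.09, -0.73, -0.89, -1.02 and -0.31 with spike-in scaling. The means of the inhibitors and myogenic regulators were -0.06 and -0.07. Of the 28 lists, 19 passed and 11 of these passed with an estimated correlation. Within each slide, all 67 called genes named by the rule and all 19 passing lists kept their sign. Dguok (0.69), Tyms (-0.85), Cdk1 (-0.21), Prim2 (-1.01) and the nuclear replication list (-0.29) were not called with normexp. Tyms (-0.29) was not called as a mean over probes, nor Dguok without myotube replicate 1 (0.92), soleus replicate 2 (0.91) or soleus replicate 3 (0.97). The macrophage list did not pass among genes above background on all 12 arrays (1.16). The de novo list did not pass with quantile normalization (-0.65), the authors' values (-0.63), the filter on all 12 arrays (-0.43), as a mean over probes (-0.23) or without myotube replicate 2 (-0.54).

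**Figure D2:**
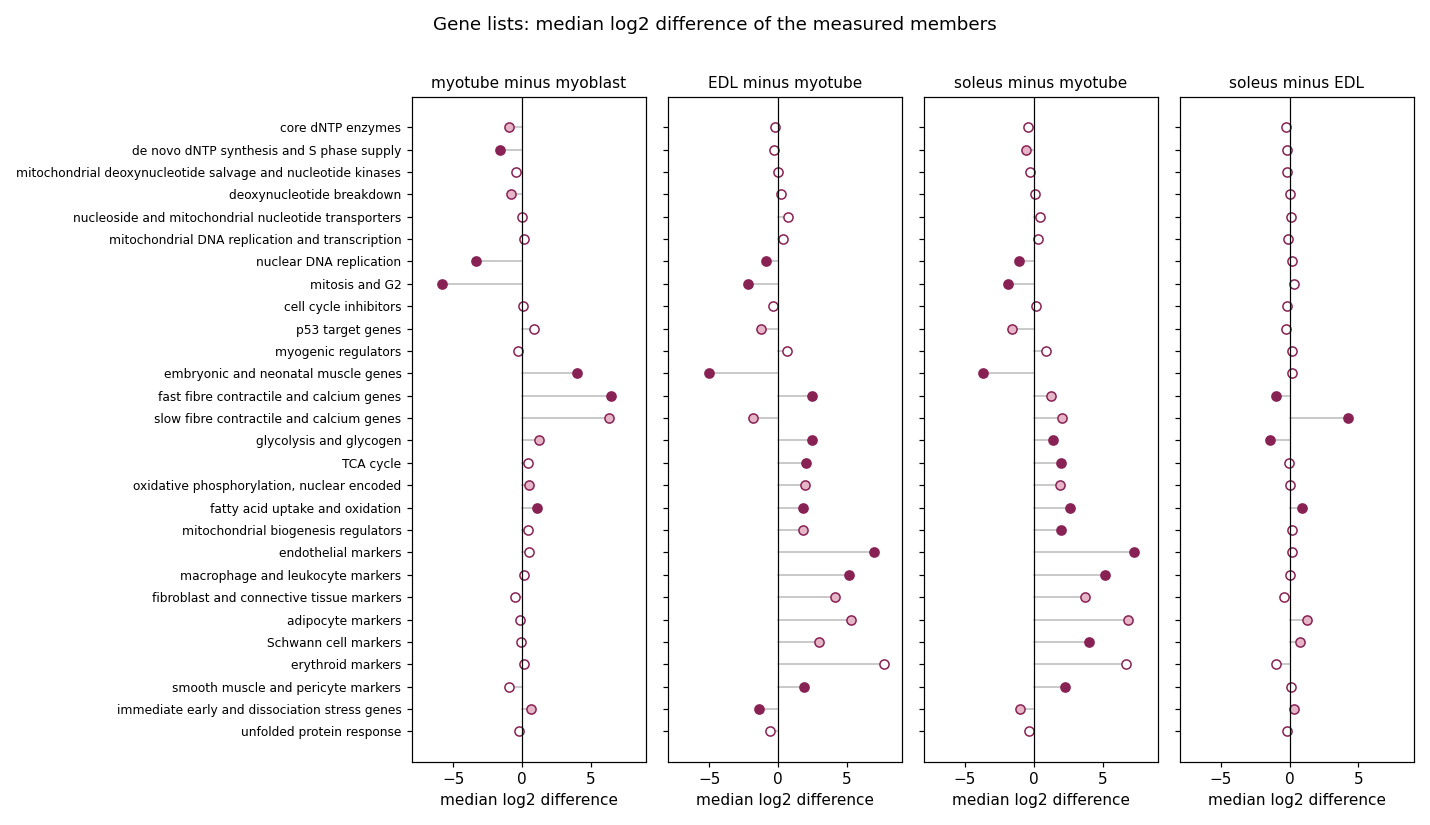
Median log2 difference of the measured members (horizontal axis) of the 28 gene lists (vertical axis) in the 4 main comparisons. Dark points passed the list test with a preset and with an estimated correlation, pale points only with the preset one, and open points with neither. The oxidative phosphorylation medians are 1.96 and 1.92 in the muscle minus myotube comparisons and 0.01 in soleus minus EDL.

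The comparison of soleus with EDL sets a slow against a fast muscle. The dNTP enzymes differed in Tk1, which was 3.00-fold lower in soleus (8.65 ± 0.23 against 10.24 ± 0.13; difference -1.59, SE 0.16, adjusted p = 5.1e-05), and in Rrm2, which was 2.07-fold higher (7.87 ± 0.10 against 6.82 ± 0.16; difference 1.05, SE 0.12, adjusted p = 9.4e-05). With normexp neither was called (-1.03 and 1.00), and Rrm2 also lost its call with spike-in scaling (0.83) and without EDL replicate 3 (0.95). Rrm1 differed by -0.95 (SE 0.07, adjusted p = 4.2e-06), just under the log2 threshold (-1.17 and called with normexp). In the list 2 of 14 enzymes changed and 2 also when adjusted over the list alone (median -0.25, adjusted p = 0.167). Tk2 (-0.10), Dguok (-0.11), Dck (-0.02), Dut (-0.58), Tyms (0.32), Rrm2b (-0.38), Samhd1 (-0.32), Nt5m (-0.19), Nt5c (-0.36) and Tymp (0.06, or -0.16 with spike-in scaling) were not called. Dctd was above background on 1 of 3 EDL arrays and no soleus array, so no difference is given for it.

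Contractile and metabolic groups differed in opposite directions. Of 12 slow fibre genes 11 were higher in soleus (median 4.26, adjusted p = 1.6e-19), led by the slow troponins Tnnc1 (6.15, SE 0.12) and Tnni1 (5.75, SE 0.09) and the slow calcium pump Atp2a2 (6.07, SE 0.11). Myl3, the member not called, stood at 0.68 and was called as a mean over all tested probes (3.41). Of 15 fast fibre genes 7 were lower (median -0.99, adjusted p = 2.1e-06), such as Pvalb (-4.78, SE 0.25), Actn3 (-4.76, SE 0.14) and Mybpc2 (-3.42, SE 0.18). Of 19 glycolysis and glycogen genes 13 were lower (median -1.42, adjusted p = 3.1e-10), including the phosphorylase kinase subunits Phkg1 (-3.74, SE 0.47) and Phka1 (-2.61, SE 0.33) and Gpd1 (-3.23, SE 0.12). Of 22 fatty acid genes 9 were higher (median 0.91, adjusted p = 8.2e-12), with Fabp3 at 1.75 (SE 0.11), Lpl at 1.67 (SE 0.08) and Cd36 at 1.5 (SE 0.15). None of the 43 oxidative phosphorylation genes and none of the 19 TCA cycle genes was called by limma (medians 0.01 and -0.05, adjusted p = 0.718 and 0.466), with 6 and 5 at an unadjusted p under 0.05. The oxidative phosphorylation median was -0.21 with spike-in scaling, and with normexp both it (-0.38) and the TCA cycle median (-0.47) passed the list test as lower in soleus. Of 6 adipocyte markers 4 were higher in soleus (median 1.27, adjusted p = 0.0239; adjusted p = 0.223 with an estimated correlation), namely Cidec (1.62, SE 0.51), Cfd (1.55, SE 0.26), Adipoq (1.43, SE 0.11) and, chosen after its values were seen, Plin1 (1.10). Of 7 Schwann cell markers Mbp was called (1.33, SE 0.08; list median 0.76, adjusted p = 0.00566; adjusted p = 0.10 with an estimated correlation). Of 14 immediate early genes 3 were higher and 1 lower (median 0.29, adjusted p = 0.0332; adjusted p = 0.108 with an estimated correlation). These were Hspa1a (2.24, SE 0.08), Atf3 (2.00, SE 0.11), Fos (1.47, chosen after its values were seen) and Nr4a1 (-1.73, SE 0.09).

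Among genes eligible by the rule, the highest difference was the cardiac myosin Myh6 (6.28, SE 0.15). Tspan8 (-5.53, SE 0.18), Cntnap2 (-4.91, SE 0.21) and Dkk3 (-4.91, SE 0.11) were the lowest of these. In all, 932 genes were higher and 905 lower in soleus (50.7% of calls higher), against 362 higher and 643 lower (36.0%) with spike-in scaling. The groups did not overlap for 44.8% of genes, where chance gives 10%. The other lists did not pass (adjusted p from 0.0718 to 0.891), among them the endothelial (0.15), macrophage (0.01), fibroblast (-0.42), smooth muscle (0.07) and erythroid (-1.02) markers, nuclear DNA replication (0.18), mitosis and G2 (0.33, or 0.31 with 1 member at its bound), p53 targets (-0.30) and biogenesis regulators (0.17). Of these medians the endothelial (-0.07), macrophage (-0.21), smooth muscle (-0.14), replication (-0.04) and biogenesis (-0.05) ones turned negative with spike-in scaling. De novo synthesis (-0.20), salvage (-0.17), breakdown (0.03), transporters (0.07), mitochondrial DNA replication (-0.09), cell cycle inhibitors (-0.20), myogenic regulators (0.18), embryonic genes (0.15) and the unfolded protein response (-0.22) completed them. The breakdown (-0.19), transporter (-0.14), myogenic (-0.03) and embryonic (-0.06) medians turned negative with spike-in scaling. The mean was -0.13 for transporters and 0.10 for cell cycle inhibitors. With normexp the de novo (-0.34), mitochondrial DNA replication (-0.31), mitosis (0.86) and p53 (-0.34) lists passed. As a mean over probes the de novo (-0.25), embryonic (0.15), biogenesis (0.49) and smooth muscle (0.20) lists passed, without a filter the mitosis (0.33) and embryonic (0.15) lists, and with the authors' values the erythroid list (-1.07). Of the 28 lists, 7 passed and 4 of these passed with an estimated correlation. Within each slide all 25 called genes named by the rule and all 7 lists kept their sign, with Tk1 at -1.74 to -1.40 and Rrm2 at 0.84 to 1.28. With normexp Cntnap2 (-2.17), Dkk3 (-2.97), Phka1 (-2.37), Fabp3 (1.41), Cd36 (1.17), Cidec (1.25), Cfd (1.23), Adipoq (1.23), Mbp (0.96) and the adipocyte (1.13), Schwann cell (0.61) and immediate early (0.24) lists lost their calls. Lost with spike-in scaling were Cd36 (1.28), Cidec (1.41), Cfd (1.33), Adipoq (1.22), Mbp (1.12) and the immediate early list (0.07). Cidec was lost without a filter (1.62) and in every fit that left out 1 EDL or soleus array. The Schwann cell (0.73) and immediate early (0.29) lists were lost among genes above background on all 12 arrays, and the immediate early list without replicate 1 of every group (0.32) or soleus replicate 1 (0.32).

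Against the dividing myoblasts, 10 of the 14 core enzymes changed in EDL (2 higher and 8 lower) and 11 in soleus (2 higher and 9 lower), with the same counts when adjusted over the list alone. The 9 lower in soleus include Samhd1 (-1.29), which stood at 0.65 as a mean over its probes and was not called with normexp (-0.82). They also include Dctd, which was not well above background on any soleus array and was not called with normexp (-1.56). Rrm2 fell by 7.09 (SE 0.12) in EDL and by 6.05 (SE 0.12) in soleus, Tyms by 5.90 and 5.59 (SE 0.09 each) and Tk1 by 3.38 and 4.96 (SE 0.16 each). Rrm2b rose by 1.69 in EDL and 1.31 in soleus (SE 0.13 each), but was not called with spike-in scaling (0.35 and -0.25) or, in soleus, with normexp (0.86). Dguok rose by 1.13 and 1.02 (SE 0.14 each) and turned to -0.21 and -0.54 with spike-in scaling. In soleus it was not called with normexp (0.86) or without myoblast replicate 1 (0.98), soleus replicate 2 (0.92) or soleus replicate 3 (0.98). Tk2 differed by -0.57 and -0.66, below the log2 threshold, and was called with spike-in scaling (-1.91 and -2.22). Nuclear DNA replication genes were lower in 22 of 22 cases in EDL (median -4.23, adjusted p = 5.2e-11) and 21 of 22 in soleus (median -4.22, adjusted p = 1.5e-10). All 43 oxidative phosphorylation genes were higher in both (medians 2.61 and 2.59; adjusted p = 0.151 and 0.140 with an estimated correlation). On the same arrays all 12 endothelial markers (medians 7.36 and 7.68, or 6.68 and 6.89 with 4 at their bound), 12 of 14 macrophage markers (5.26 and 5.17, or 4.41 and 4.29 with 8 at their bound) and all 6 adipocyte markers (5.17 and 6.69, or 4.57 and 6.10 with 3 at their bound) were higher. With an estimated correlation none of these 3 lists passed (adjusted p = 0.0765 and 0.0659 for endothelial, 0.0765 and 0.0518 for macrophage, 0.151 and 0.124 for adipocyte markers). The core list passed in both comparisons (adjusted p = 0.00291 and 0.00190; adjusted p = 0.131 and 0.119 with an estimated correlation). In all, 6360 genes were higher and 4573 lower in EDL (58.2% of calls higher), against 25.2% with spike-in scaling and 47.7% with the authors' values, and 5910 were higher and 4551 lower in soleus (56.5%), against 21.1% with spike-in scaling.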

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

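The counts of other splits were planned before the data were examined, whereas the tests of the muscle differences, the percentile of signal, Rrm2 and Tk1 were chosen only after the results were seen.

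Of the 67 genes named in both muscle minus myotube comparisons, 17 differed between the muscles by the direct test of soleus minus EDL, 11 higher and 6 lower in soleus. Slow troponin Tnnc1 differed by 6.15 (SE 0.12): it fell by 5.92 from myotubes to EDL and stood at 0.24 in soleus (-0.97 with spike-in scaling). The slow myosin Myh7 differed by 3.31 (SE 0.12), with -0.75 in EDL and 2.56 in soleus minus myotube; the EDL value was -1.58 with quantile normalization, -1.55 with the authors' values and -1.74 with spike-in scaling, and called with each. Lpl (1.67), Ppara (1.19), Cfd (1.55), Adipoq (1.43) and Mbp (1.33) were above the myotubes in both muscles and further so in soleus. The receptor subunit Chrng (1.64), Cdkn1a (1.13) and Rrm2 (1.05) were below the myotubes in both muscles and less so in soleus. The 17 include Cdk1 with a fitted value of 1.23, but it was above background on 1 of 3 soleus arrays and on 0 of 3 EDL arrays, so no difference between the muscles is read from it. Tk1 (-1.59, SE 0.16), Fbp2 (-1.60), Atp2a1 (-1.75), Gpd1 (-3.23), Phkg1 (-3.74) and Pvalb (-4.78) were lower in soleus than in EDL. The alternatives that end the calls of Rrm2, Tk1, Cfd, Adipoq and Mbp are given in the report.

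Each comparison of 3 arrays against 3 allows 10 splits, too few for a share under 0.05, and 1 split, the real one, called as many genes as the real split in every comparison. Every other split mixes arrays of the groups compared, so their differences enter its residual spread and low counts follow. The counts of the other splits are therefore no measure of the calls that chance would give. The real split called 6688 genes in myotube minus myoblast, 9048 in EDL minus myotube, 8563 in soleus minus myotube, 10933 in EDL minus myoblast and 10461 in soleus minus myoblast, and the highest other split 0 in each. In soleus minus EDL the real split called 1837 genes and the highest other 1. Since the numbers pair the samples, the real split compares with the 3 others that part every slide pair, which called 0 genes in each comparison. The other 6 keep slide pairs together, and the highest count among these in soleus minus EDL was 1 gene.

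The 75th percentile of signal was lower on muscle than on culture arrays (-1.19 on the log2 scale). Weaker labelling or scanning of the muscle arrays needs dimmer spike-in probes, and these differed by 0.0771 in the other direction, which argues against it. A few very bright genes taking the signal, as the whole cause, needs an equal summed signal, and the sum was lower by -0.67 on muscle arrays (77.9 to 107 megaunits of intensity against 121 to 195). The brightest 100 probes nevertheless held 25.4% to 28.0% of the signal on muscle arrays and 16.3% to 18.1% on culture arrays, so such genes may account for part of the difference. A smaller variety of abundant RNAs in adult muscle than in cultured cells is a possible biological explanation that was not tested.

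Rrm2 kept 15.2% of its myoblast level in myotubes. Cycling myoblasts left among the myotubes, as the whole cause, would carry the mitosis and G2 transcripts along at the same share or more. Those genes kept a median of 1.77%, with 18 of 18 below Rrm2 and a highest of 3.17%, which argues against it. Nuclear DNA replication genes kept a median of 9.98%, with 17 of 22 below Rrm2 and a highest of 26.3%. S phase genes were mixed: Rrm1 kept 47.8%, while Tk1, Cdc6, Mcm5 and Mcm10 kept less than the highest mitosis gene. Slower loss of S phase transcripts than of mitotic ones stays open for part of these genes only, as a biological explanation that was not tested.

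Tk1 was lower in soleus than in EDL by -1.59 (slides -1.74 to -1.40). More cycling cells in the EDL samples would lower the replication genes by about as much, and the 18 above background in both muscles had a median of 0.13 (SD 0.54, -0.98 to 0.90), which argues against it; Aurka (-3.66) of the mitosis list, chosen after its values were seen, went the other way. The 3 erythroid markers had a median of -1.02 (-1.20 to -1.01), lower in soleus but by less than Tk1; the list passed only with the authors' values (-1.07). More blood in the EDL samples cannot be told apart from a difference in muscle fibres, because few markers were measured and a share of Tk1 from blood cells was not estimated. A difference between the fibre types themselves stays open and was not tested.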

How the results depend on the processing

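The fit without replicate 1 of every group was chosen only after the results were seen; the other alternatives were planned. The normexp, spike-in, filter and probe settings changed counts as follows, and the cause was not tested unless one is given.

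With normexp background the counts were 1621 higher and 1802 lower in myotube minus myoblast, 2703 and 2189 in EDL minus myotube, 2521 and 2273 in soleus minus myotube (3 core enzymes), 154 and 302 in soleus minus EDL (1 core enzyme), 2950 higher in EDL minus myoblast, and 2373 and 2901 in soleus minus myoblast (7 core enzymes). Directions reversed for Fbp2 in myotube minus myoblast (-0.35), for Dctd (1.06), Bub1 (0.54) and Aurkb (0.73) in soleus minus myotube, and for the oxidative phosphorylation median in soleus minus EDL (-0.38). Normexp also moved the median over all genes, from 0.06 to -0.54 in myotube minus myoblast and from 0.15 to 0.58 in soleus minus myotube. In soleus minus EDL that median moved from -0.05 to 0.24. The reversed genes went the way of this move, and the oxidative phosphorylation median went against it.

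With spike-in scaling the counts were 2644 higher and 7717 lower in EDL minus myotube and 2248 and 9173 in soleus minus myotube (11 core enzymes). They were 362 higher in soleus minus EDL (1 core enzyme), 3065 and 9085 in EDL minus myoblast, and 2760 and 10303 in soleus minus myoblast. Some calls were lost on the adjusted p. In soleus minus EDL the lower count fell from 905 to 643 against a downward shift of -0.22. There Cd36 (1.28), Cidec (1.41) and Cfd (1.33) kept a log2 difference over 1 but were no longer called. By construction this scaling shifts the log2 difference of every gene of a comparison alike. Among values called in at least 1 of the 2 fits, that shift reversed Dguok (-0.19), Dut (-1.09), Nt5m (-1.09), Mcm3 (-1.17) and Nrf1 (-1.14) in soleus minus myotube, Dguok in EDL minus myoblast (-0.21), and Dguok (-0.54) and Rrm2b (-0.25) in soleus minus myoblast.

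Without a filter on dim probes more genes were tested, and 8139 were higher in EDL minus myotube, 11999 in EDL minus myoblast and 10996 in soleus minus myoblast. With genes well above background on all 12 arrays fewer were tested, and 3432 were higher in EDL minus myotube, 3093 in soleus minus myotube and 3863 in soleus minus myoblast, with 527 higher and 568 lower in soleus minus EDL. As a mean over all tested probes Samhd1 reversed to 1.19 in EDL minus myotube, 1.52 in EDL minus myoblast and 0.65 in soleus minus myoblast, because its 2 probes differed in direction.

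Leaving out each array in turn, the core enzymes called in soleus minus EDL ranged from 1 (without EDL replicate 3) to 3 (without soleus replicate 1, where Dctd, above background on 1 of 3 EDL arrays and 0 of 3 soleus arrays, is the added one). The other counts stayed within 1.5 times, for example 866 to 973 higher and 827 to 1005 lower in soleus minus EDL. Of 306 counts under alternatives 34 moved by more than 1.5 times. Of 5039 values of named genes under alternatives 4910 kept their side of the threshold, and their direction where called; 77 of these, called in neither fit, changed sign. Another 51 were weaker, 63 stronger and 15 reversed. Of 1896 list values 1833 kept their side and, where they passed, the direction of the list test, and in 75 of these, passing in neither fit, the median changed sign; 28 were weaker, 34 stronger and 1 reversed. The mitosis list in soleus minus myotube with normexp is among the weaker ones by its test, though its median turned to 0.28. The paired fit with the replicate block changed the call of 1 of 301 named genes, Fosb in soleus minus myotube (-1.01), and of no gene list. Among all genes it moved the counts, for example to 978 higher and 999 lower in soleus minus EDL, where it shared all 1837 calls, and to 5567 and 3709 in EDL minus myotube, where it shared 9037 of 9048. Genes dim in a group, such as Dctd, Bub1 and Upp1, are limited by signal over background.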

Other observations

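The genes below were chosen only after their values were seen, and no explanation was tested for them.

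Some members of the lists differed between the muscles or between cultures and muscle in ways their list's median does not show. The mitotic kinase Aurka stood at 14.87 in myoblasts, 9.55 in myotubes, 12.72 in EDL and 9.06 in soleus (1 probe). The nucleoside transporter Slc28a2 was not well above background on any myotube array and was at least 97.4-fold higher in EDL and at least 110-fold higher in soleus. The mitochondrial adenylate kinase Ak4 differed by -2.27 in myotube minus myoblast, 3.04 in EDL minus myotube and 1.37 in soleus minus myotube (SE 0.14 each), and the pyrimidine catabolic enzyme Dpyd by 3.24 and 5.16 (SE 0.18 each) in EDL and soleus minus myotube. Cytidine deaminase (Cda) differed by 1.70 (SE 0.25) in soleus minus EDL.

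Myogenic regulators went both ways. From myoblasts to myotubes Mef2c differed by 6.34 (SE 0.18), Mymk by 4.81 (SE 0.48), Myog by 3.95 (SE 0.08) and Myf6 by 3.30 (SE 0.16), while Msc was at least 17.6-fold lower. Against myotubes, Myog differed by -6.80 in EDL and -5.01 in soleus, Mymk by -6.08 and -6.30, and Myf6 by 4.94 and 4.52. Myod1 differed by -1.74 in EDL and -3.47 in soleus minus myotube and by -1.74 in soleus minus EDL (SE 0.11 each).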
